A study of Mus musculus with 12 samples.

How the data were processed

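RNA sequencing was done on frontal cortex of male C57BL/6 mice. Per the labels' protocols, RNA was extracted with an RNeasy kit and made into Illumina mRNA libraries. The 12 libraries form 4 groups of 3: wild type or labelled conditional Hdac2 knockout, each given vehicle or chronic clozapine at 10 mg/kg. Per the submitters' processing notes, reads were aligned to the mouse genome GRCm38 with STAR 2.5.1b and counted per gene with featureCounts. The deposited values are estimated counts per gene: some are not whole numbers, as when a read is shared between genes. Whole counts had been assumed before the data were examined. The values were therefore rounded to whole numbers for the tests, and the unrounded ones were tried as an alternative. How reads of more than 1 gene were shared, and whether strand was used, is not stated, so values of near-identical, overlapping or antisense genes are uncertain.

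Gene identifiers were matched without their version to the GENCODE mouse annotation, release 21 (GRCm38), which named 46488 of 47069. Genes were kept where edgeR's filterByExpr found enough counts, which left 17286, leaving out 29783 and keeping 99.9% of counts. Total counts per library lie between 23408372 and 28069638. Replicates vary by more than counting error, so precision is set by the spread between libraries. Expression is given as CPM, counts over TMM-scaled library sizes, as mean and SD of 3 libraries.

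All 7 contrasts were tested in 1 fit of the 12 libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, a robust quasi-likelihood fit and BH adjustment over the tested genes with a threshold of 0.05. They are clozapine against vehicle in each genotype, labelled knockout against wild type under each treatment, the interaction (effect of clozapine in the labelled knockout minus that in wild type), and clozapine and genotype effects each averaged over the other factor. The labels do not say more about the animals than group and number, so the p-values measure the spread between these libraries. The labels do not say that replicate numbers tie libraries of different groups to each other, and no pairing was used in the reported tests.

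Lists of genes were written by hand before the data were examined, 18 of pathways and 18 of cell markers. The pathway lists are histone deacetylases, HDAC1/2 co-repressor complexes, excitatory synapse and plasticity genes, activity-induced immediate early genes, metabotropic glutamate receptors, monoamine, muscarinic and histamine receptors, GABA receptors and transporters, NF-kB pathway and targets, cholesterol synthesis, fatty acid synthesis, circadian clock genes, glucocorticoid-responsive genes, unfolded protein response, heat shock proteins, voltage-gated potassium and sodium channels, nuclear-encoded respiratory chain, mitochondrially encoded proteins and cytosolic ribosomal proteins. The cell lists are excitatory neurons, upper-layer neurons, deep-layer neurons, interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells, mural cells, meningeal fibroblasts, choroid plexus, ependymal cells, red blood cells, striatal projection neurons, hippocampal granule neurons, olfactory bulb neurons and thalamic neurons. Each with at least 3 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with BH adjustment over the lists of a contrast. The hippocampal granule neuron list had 2 tested members and was not tested, which leaves 35. Camera with an estimated correlation and fry were run as alternatives.

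The genes named in the text follow a rule made before the data were examined. Hdac2 comes first in every library. For each contrast up to 12 higher and 12 lower genes are named, those with the largest log2 change among genes past the threshold with a mean of at least 1 CPM and no overlap between the compared libraries. The overlap was not required for the interaction, and symbols of predicted genes, clone names and pseudogenes were left out. Where fewer than 10 genes passed, the 10 of smallest p are eligible as not passing. From each list up to 4 members past the adjustment over the list alone are named by smallest p, or the 2 of smallest p where none passes. The text gives those that bear on each comparison, and says where a gene was chosen after its values were seen. Results for some genes under the rule are not reported.

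Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors in edgeR, no low-count filter beyond 1 count, a mean CPM of at least 1, a replicate block, 1 surrogate variable from sva 3.50.0, a threshold of 0.10, leaving out each library in turn, and fits of only the 2 groups compared. A smooth correction of each library for gene length and GC content (17197 genes, 99.5% of those tested, have values) and the unrounded counts were added after seeing the data.

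The tests were checked on simulated counts drawn from the libraries' own means and sizes over 17286 genes, with known changes. Changes of 1.25, 1.5 and 2-fold were called in 40.3%, 65.7% and 81.8% of genes for clozapine in wild type, and in 34.3%, 61.2% and 78.8% for clozapine in the labelled knockout. The shares were 28.4%, 62.7% and 78.8% for the genotypes under vehicle, 28.4%, 73.1% and 83.3% under clozapine, and 11.9%, 53.7% and 72.7% for the interaction. They were 59.7%, 76.1% and 89.4% for averaged clozapine and 46.3%, 67.2% and 90.9% for averaged genotype. Of 17061 unchanged genes 4 to 13 were called. Camera called a changed set of 25 genes in all 7 simulated contrasts, also with an estimated correlation, and 0 of 35 unchanged sets. Genes were drawn independently of each other, so the simulation does not check calls of lists whose genes are correlated.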

Results

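RNA from the frontal cortex of male C57BL/6 mice was sequenced in 12 libraries, 3 in each of 4 groups. Wild-type mice and mice labelled as conditional Hdac2 knockouts were given vehicle or clozapine. Clozapine is an antipsychotic drug that binds serotonin, dopamine, histamine, muscarinic and adrenergic receptors, and the labels give a chronic dose of 10 mg/kg. Hdac2 encodes a histone deacetylase, an enzyme that removes acetyl groups from histones. Libraries are named here by group and number: wild-type vehicle 1, 3 and 4, wild-type clozapine 2, 3 and 5, knockout vehicle 2, 4 and 5, and knockout clozapine 3, 4 and 5. In that order the total counts were 23408372, 26069440 and 25623402, then 23652979, 23918651 and 23596197, then 24414167, 24128529 and 28069638, and last 24253847, 23788014 and 24373123. Of 47069 annotated genes, 17286 had enough counts to be tested, and expression is given as counts scaled to library size (CPM). Libraries of 1 group differed by more than counting error, with a chi-square per gene of 4.36 to 10.3 over the 12 pairs of replicates. The first principal component held 20.3% of the variance and placed the wild-type libraries at -19.8 to -8.50 and the labelled knockout libraries at 8.49 to 18.05.

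Averaged over treatments, Hdac2 transcripts were not lower in the libraries labelled knockout. Hdac2 (ENSMUSG00000019777.16, chromosome 10, 36974544 to 37001889, GRCm38) was at 75.7, 63.4 and 70.0 CPM in wild-type vehicle and 75.5, 72.4 and 73.5 CPM in wild-type clozapine. It was at 75.4, 76.6 and 73.3 CPM in knockout vehicle and 73.9, 70.5 and 71.2 CPM in knockout clozapine. Averaged over both treatments, the labelled knockout differed from wild type by 0.03 on the log2 scale (SE 0.04, 95% interval -0.05 to 0.12, edgeR quasi-likelihood test, BH adjusted p = 0.651, n = 6 against 6), and the lower end of the interval is a fall of 3.53%. The difference was 0.11 under vehicle (edgeR adjusted p = 0.278) and -0.04 under clozapine (edgeR adjusted p = 0.804), where the interval reaches a fall of 10.6%. The counts cover the whole gene, and exons outside a deleted part are counted too, so they do not check a deletion of single exons. The genotype is therefore written as labelled throughout, and every genotype direction below rests on the labels.

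**Figure D1:**
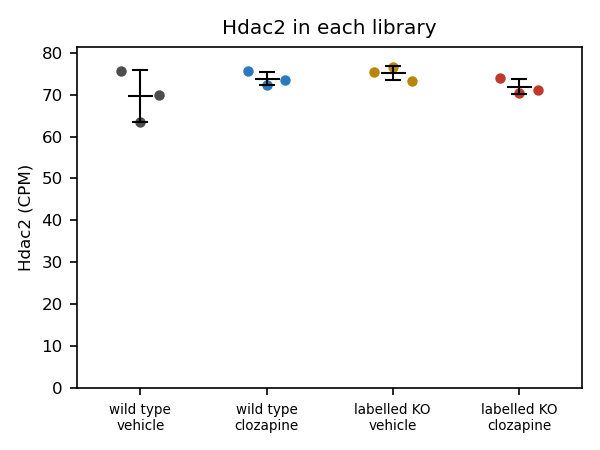
Hdac2 expression in CPM (vertical axis) for each library (points) in the 4 groups (horizontal axis), with the group mean and SD as bars. The 12 libraries lie between 63.4 and 76.6 CPM, and the labelled knockout and wild-type libraries overlap.

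The number of genes past the threshold differed widely between the comparisons. By edgeR's quasi-likelihood test at a BH adjusted p under 0.05, 141 genes passed for clozapine in wild type and 4 for clozapine in the labelled knockout. The difference between these counts depends on the method: DESeq2 called 285 and 285, edgeR with 1 surrogate variable 201 and 209, and 2004 and 2117 genes had an unadjusted p under 0.05. For labelled knockout against wild type, 1584 genes passed under vehicle and 345 under clozapine. Across 17197 genes, which are not independent replicates, log2 changes had Spearman correlations with exonic length, GC content and expression. For clozapine they were -0.0469, -0.167 and -0.130 in wild type and 0.182, 0.125 and 0.196 in the labelled knockout. For the genotypes they were -0.209, -0.0165 and -0.203 under vehicle and -0.0359, 0.232 and 0.0545 under clozapine. In the interaction they were 0.163, 0.192 and 0.230. Gene lists were tested with camera, which asks whether the genes of a list moved together relative to the other genes. With its preset correlation of 0.01, camera called 62 of 245 list tests (35 lists in 7 comparisons), 30 up and 32 down. With the correlation estimated from the data camera called 0, where 16 of the 245 had an unadjusted p under 0.05, and fry, which tests whether a list's genes move one way on balance, called 11, among them the unfolded protein response in 3 comparisons. A list described below as called, or as moved, higher or lower, passed camera at the preset correlation, and each adjusted p with an estimated correlation is camera's too. The median, mean and camera direction of a list differed in sign in 37 of the 245 tests and in 0 of the 62 called.

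**Figure D2:**
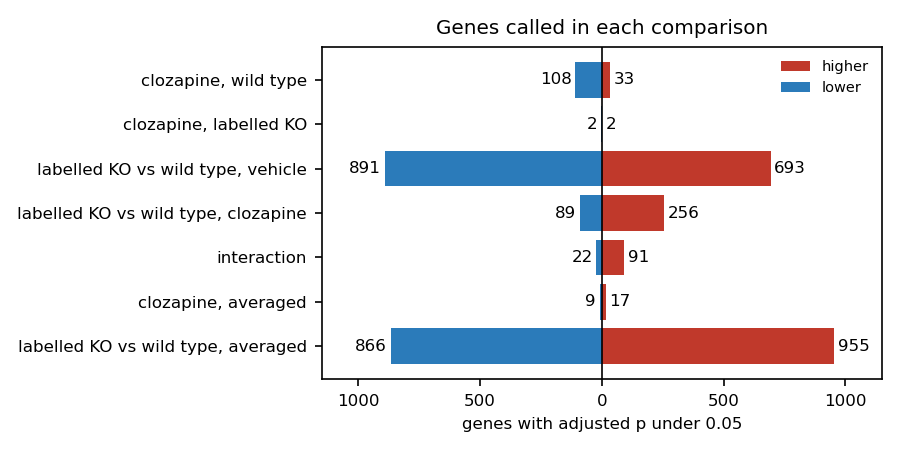
Number of genes (horizontal axis) past a BH adjusted p of 0.05 by edgeR's quasi-likelihood test in each of the 7 comparisons (vertical axis), split into higher and lower expression. Labelled knockout against wild type under vehicle has 693 higher and 891 lower genes, and clozapine in the labelled knockout has 2 and 2.

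Which genes clozapine changes in wild-type cortex was the first question. Hspa5 (ENSMUSG00000026864.13, chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, fell from 371 ± 24.6 CPM with vehicle to 261 ± 7.06 CPM with clozapine (SD, n = 3 each), a log2 change of -0.51 (SE 0.05, edgeR adjusted p = 0.00036). Dbp (ENSMUSG00000059824.10, chromosome 7, 45705088 to 45710203), a transcription factor driven by the circadian clock, fell by 0.62 (SE 0.07, edgeR adjusted p = 0.00059). Nr1d1, a repressor within the clock, fell by 0.54 (SE 0.06, edgeR adjusted p = 0.00036). Apod, which encodes a lipid-binding apolipoprotein, rose from 84.2 ± 4.92 to 123 ± 4.20 CPM (log2 change 0.54, SE 0.07, edgeR adjusted p = 0.0023). Each of these 4 genes also passed in all 12 tests that left out 1 library. In total edgeR's quasi-likelihood test called 141 genes, 33 higher and 108 lower, of which 18 passed in all 12 such tests. The 3 libraries of each group did not overlap for 15.6% of genes, where chance gives 10%. The count was 20 without wild-type vehicle 3, 36 without wild-type clozapine 5, 71 without wild-type vehicle 1, 89 without knockout clozapine 4, 91 without wild-type clozapine 2 and 219 without knockout vehicle 5. DESeq2 called 285 genes, edgeR with no low-count filter 304, edgeR on the 2 groups alone 92, and a threshold of 0.10 gave 260.

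Genes of the unfolded protein response, which refold or clear proteins in the endoplasmic reticulum, were lower after clozapine in wild type. Of 16 measured members 5 fell and 0 rose (8 and 0 adjusted over the list alone), with a median log2 change of -0.19 (camera adjusted p = 1.9e-09; adjusted p = 0.186 with an estimated correlation). Beside Hspa5, the disulfide isomerase gene Pdia6 fell by 0.35 (edgeR adjusted p = 0.0082, but 0.057 without wild-type vehicle 3). The chaperone gene Calr fell by 0.25 (edgeR adjusted p = 0.013, but 0.087 without wild-type vehicle 3 and 0.068 without wild-type clozapine 5). Genes of cholesterol synthesis moved the other way: 3 of 25 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 5.3e-13; adjusted p = 0.186 with an estimated correlation). Of 17 circadian clock genes 2 fell, Dbp and Nr1d1, and 0 rose (4 and 1 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 5e-05; adjusted p = 0.229 with an estimated correlation). Clock genes vary over the day, and the labels do not state the hour at which tissue was taken, so here and below a difference in that hour between groups is not separated from drug or genotype for these genes.

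Markers of other cells moved in the same comparison of wild-type clozapine with vehicle. Red blood cell genes had a median log2 change of 0.86 (5 genes, 0 passing alone; adjusted p = 0.599 with an estimated correlation), and Hba-a1 was at 39.1 to 47.1 CPM with vehicle and 55.1 to 113.7 CPM with clozapine. Oligodendrocyte markers had a median of 0.13 (0 of 11 passing; adjusted p = 0.987 with an estimated correlation), and this camera call ended without wild-type vehicle 1 (adjusted p = 0.38), wild-type clozapine 2 (0.12) or wild-type clozapine 3 (0.24). Meningeal fibroblast markers had a median of 0.26 (0 of 8 passing; adjusted p = 0.987 with an estimated correlation), lost without wild-type vehicle 1 (camera adjusted p = 0.079), wild-type vehicle 4 (0.086), wild-type clozapine 2 (0.095) or wild-type clozapine 5 (0.32). Choroid plexus markers had a median of -1.04 (0 of 5 passing; adjusted p = 0.987 with an estimated correlation). A member, Ttr, was at 53.3 CPM in wild-type vehicle 3 and at 0.29 to 4.15 CPM in the other 11 libraries. That list's call ended without wild-type vehicle 3 (camera adjusted p = 0.47), wild-type clozapine 2 (0.11), wild-type clozapine 3 (0.090) or wild-type clozapine 5 (0.11). Excitatory synapse genes had a median of -0.04 with 1 of 28 falling (3 adjusted over the list alone; adjusted p = 0.987 with an estimated correlation), a call lost without wild-type clozapine 5 (0.11). Cytosolic ribosomal protein genes had a median of 0.03 (0 of 75 passing; adjusted p = 0.987 with an estimated correlation), a call lost without wild-type vehicle 3 (0.995) or wild-type clozapine 2 (0.81). The ribosomal and choroid plexus calls also ended after a correction for gene length and GC content that was added after the data were seen (adjusted p = 0.316 and 0.0603).

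Clozapine in the labelled knockout asks whether the drug acts on these genes with Hdac2 targeted. Amer2, a regulator of Wnt signalling, rose from 15.4 ± 1.35 to 22.2 ± 1.70 CPM (SD, n = 3 each; log2 change 0.53, SE 0.08, edgeR adjusted p = 0.045), and Tnrc18 rose from 119 to 151 CPM (log2 change 0.34, edgeR adjusted p = 0.045). Rn7s1 and Rn7s2, near-identical copies of the RNA of the signal recognition particle, had log2 changes of -1.84 and -1.86 (edgeR adjusted p = 0.0085 for both), and their values are uncertain because reads cannot be told apart between the copies. DESeq2 gave Rn7s1 and Rn7s2 no adjusted p, since its low-count filter left them out, and edgeR no longer called them without knockout clozapine 4 (adjusted p = 0.067) or knockout clozapine 5 (0.13). The Amer2 call ended without wild-type vehicle 3 (edgeR adjusted p = 0.083), knockout vehicle 2 (0.076), knockout vehicle 5 (0.13), knockout clozapine 3 (0.13), knockout clozapine 4 (0.067) or knockout clozapine 5 (0.18), and that of Tnrc18 without wild-type vehicle 3 (0.083), wild-type vehicle 4 (0.050), wild-type clozapine 3 (0.084), knockout vehicle 5 (0.079), knockout clozapine 3 (0.13), knockout clozapine 4 (0.20) or knockout clozapine 5 (0.18). Both ended with limma-voom (0.086 for Amer2), with RLE size factors (0.053) and after a correction for gene length and GC content added after the data were seen (0.055 for Amer2 and 0.10 for Tnrc18). Hspa5, which fell in wild type, was at 222 ± 4.87 CPM with vehicle and 235 ± 8.97 CPM with clozapine and did not pass. In total edgeR's quasi-likelihood test called 4 genes (2117 at an unadjusted p under 0.05, against 864 by chance). The 3 libraries of each group did not overlap for 18.7% of genes, where chance gives 10%. None of the 4 held throughout: 0 genes passed without knockout clozapine 4 or without knockout clozapine 5, 2 without knockout clozapine 3 or wild-type vehicle 3, 9 without wild-type clozapine 5, 15 without wild-type clozapine 2, 23 without wild-type vehicle 1 and 25 without knockout vehicle 4. DESeq2 called 285 genes (227 higher), limma-voom 2, edgeR with RLE size factors 2, with no low-count filter 213, with 1 surrogate variable 209, on the 2 groups alone 7, after the length and GC correction 2, and a threshold of 0.10 gave 113.

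Neuronal gene lists moved together after clozapine in the labelled knockout while 0 of their genes passed over all genes, in a comparison with trends over all genes. Log2 changes there correlated with exonic length (Spearman 0.182), GC content (0.125) and expression (0.196). Voltage-gated potassium and sodium channel genes, which set how neurons fire, had a median log2 change of 0.16 (7 of 17 higher adjusted over the list alone; camera adjusted p = 6e-08; adjusted p = 0.478 with an estimated correlation). Kcna2, a member, was at 290 CPM with vehicle and 362 CPM with clozapine (log2 change 0.32, edgeR adjusted p = 0.073). Upper-layer neuron markers had a median of 0.20 (2 of 6 higher adjusted over the list alone; adjusted p = 0.478 with an estimated correlation), and Cux2 was at 156 and 194 CPM. Deep-layer markers had a median of -0.34 (0 of 8; adjusted p = 0.663 with an estimated correlation). The 13 proteins encoded by the mitochondrial genome had a median of -0.21 (0 passing; adjusted p = 0.701 with an estimated correlation), which was -0.05 and no longer called after the length and GC correction (adjusted p = 0.176). That correction also ended the calls of the excitatory synapse genes (median 0.06, 6 higher and 1 lower of 28 adjusted over the list alone; adjusted p = 0.701 with an estimated correlation) and of the HDAC1/2 co-repressor complexes (median 0.05, 0 of 23; adjusted p = 0.478 with an estimated correlation). Interneuron markers (median 0.13, 3 of 13 higher adjusted over the list alone; adjusted p = 0.478 with an estimated correlation) lost their call without knockout vehicle 4 (0.17).

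The other calls of that comparison each depended on single libraries. Monoamine, muscarinic and histamine receptor genes, the drug's targets, had a median of 0.11 (3 of 19 higher adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). GABA receptor and transporter genes had a median of 0.05 (1 of 16 adjusted over the list alone; adjusted p = 0.701 with an estimated correlation). Both calls ended without knockout vehicle 5 (camera adjusted p = 0.14 and 0.24), as did those of the synapse genes (0.36) and the HDAC1/2 complexes (0.12), and the GABA call also ended without knockout clozapine 5 (0.15) and the HDAC1/2 call without knockout clozapine 4 (0.057). Circadian clock genes had a median of 0.05 (2 of 17 higher adjusted over the list alone; adjusted p = 0.602 with an estimated correlation), lost without knockout vehicle 2 (0.38) or knockout clozapine 4 (0.064). Microglial markers had a median of -0.09 (0 of 12; adjusted p = 0.711 with an estimated correlation), lost without knockout vehicle 2 (0.059), knockout vehicle 5 (0.12) or knockout clozapine 4 (0.58). Meningeal fibroblast markers had a median of 0.29 (1 of 8 higher adjusted over the list alone; adjusted p = 0.701 with an estimated correlation), lost without knockout vehicle 4 (0.29) or knockout clozapine 3 (0.051).

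The interaction asks whether the effect of clozapine differs between the genotypes as labelled. Hspa5 fell with clozapine in wild type and not in the labelled knockout, and the difference of the effects was 0.59 on the log2 scale (SE 0.08, edgeR adjusted p = 0.0019). For Dbp the difference was 0.81 (SE 0.10, edgeR adjusted p = 0.0019): its means were 99.8 ± 7.02 and 64.8 ± 4.16 CPM in wild type, and 116 ± 4.16 and 132 ± 11.3 CPM in the labelled knockout (vehicle and clozapine, SD, n = 3 each). Cux2 (ENSMUSG00000042589.18, chromosome 5, 121856366 to 122050102), a transcription factor of upper-layer neurons, had means of 194 ± 17.2 and 159 ± 9.16 CPM in wild type and 156 ± 7.57 and 194 ± 3.42 CPM in the labelled knockout (difference 0.61, SE 0.09, edgeR adjusted p = 0.0080). Eln, which encodes elastin, had a difference of 1.04 (SE 0.15, edgeR adjusted p = 0.0068), and Nr1d1 one of 0.52 (SE 0.08, edgeR adjusted p = 0.010). These 5 passed in all 12 tests that left out 1 library, as did 12 of the 113 called genes in total. In total edgeR's quasi-likelihood test called 113 genes, 91 with a higher and 22 with a lower effect in the labelled knockout, and in 87 the effect was negative in wild type and positive in the labelled knockout. Of the 113, 56 were also called for clozapine in wild type, 2 for clozapine in the labelled knockout and 83 between the genotypes under vehicle. In 108 the wild-type drug effect and the vehicle genotype effect had the same sign. These comparisons share libraries with the interaction, wild-type vehicle among them, so part of this overlap follows from the selection of the genes. The count was 13 without knockout clozapine 5, 19 without wild-type vehicle 3, 21 without knockout clozapine 3, 23 without wild-type clozapine 5, 24 without knockout clozapine 4, 40 without knockout vehicle 5, 54 without knockout vehicle 2 or wild-type vehicle 1, and 181 without knockout vehicle 4. DESeq2 called 354 genes, edgeR with no low-count filter 302, with 1 surrogate variable 290, after the length and GC correction 60, and a threshold of 0.10 gave 258.

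**Figure D3:**
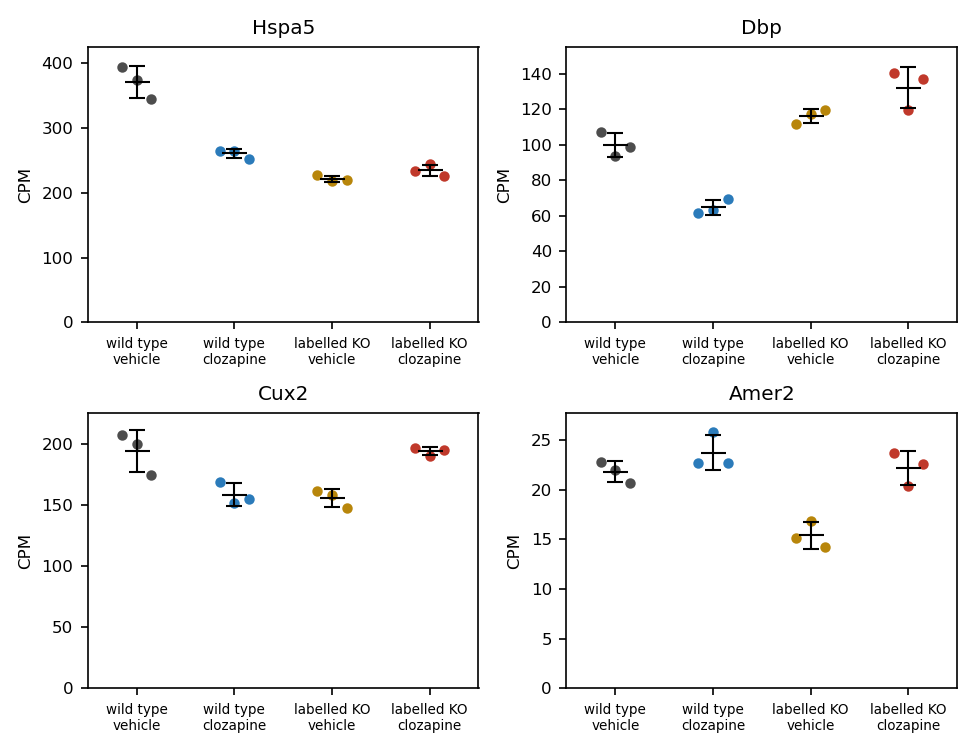
Expression in CPM (vertical axes) of Hspa5, Dbp, Cux2 and Amer2 in each library (points) of the 4 groups (horizontal axes), with the group mean and SD as bars. Hspa5 is highest in wild-type vehicle (371 CPM) and at 222 to 261 CPM in the other 3 groups.

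The same lists moved in the interaction. Cholesterol synthesis genes had a median difference of -0.25 (0 of 25 passing, 12 lower adjusted over the list alone; camera adjusted p = 5.4e-09; adjusted p = 0.29 with an estimated correlation). The unfolded protein response had a median of 0.24 with 4 of 16 higher, Hspa5, Manf, Pdia4 and Pdia6 (9 higher and 2 lower adjusted over the list alone; adjusted p = 0.311 with an estimated correlation). Of these only Hspa5 held in all 12 removals. The other 3 lost their edgeR calls without wild-type vehicle 1 or 3, wild-type clozapine 3 or 5, knockout vehicle 2 or 5, or knockout clozapine 3, 4 or 5. Manf and Pdia4 also lost them without wild-type clozapine 2, and Manf without knockout vehicle 4. The highest edgeR adjusted p were 0.13 for Manf (wild-type clozapine 5), 0.11 for Pdia4 (knockout clozapine 4) and 0.084 for Pdia6 (wild-type vehicle 3). With limma-voom Manf and Pdia4 did not pass (adjusted p = 0.068 and 0.061), and Manf did not after the length and GC correction (edgeR adjusted p = 0.055). Circadian clock genes, for which the hour of collection is not stated, had a median of 0.20 with 2 of 17 higher, Dbp and Nr1d1 (4 and 0 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). Upper-layer markers had a median of 0.21 with 1 of 6 higher, Cux2 (2 adjusted over the list alone; adjusted p = 0.503 with an estimated correlation), and deep-layer markers a median of -0.44 (0 of 8; adjusted p = 0.539 with an estimated correlation). Excitatory synapse genes had a median of 0.07 with 2 of 28 higher, Shank2 and Shank3 (5 adjusted over the list alone; adjusted p = 0.535 with an estimated correlation). Both edgeR calls ended without wild-type vehicle 1 or 3, wild-type clozapine 3 or 5, or knockout clozapine 3, 4 or 5. The Shank2 call also ended without wild-type clozapine 2 or knockout vehicle 2, and the Shank3 call without knockout vehicle 5. The highest edgeR adjusted p were 0.13 for Shank2 and 0.10 for Shank3 (both without wild-type clozapine 5). After the length and GC correction neither passed (edgeR adjusted p = 0.066 and 0.20). Shank2 did not pass with limma-voom (0.061) or RLE size factors (0.051). Channel genes had a median of 0.19 (0 of 17, 1 adjusted over the list alone; adjusted p = 0.574 with an estimated correlation). Calls that ended without single libraries were those of the receptors (median 0.18, 2 higher and 1 lower of 19, 4 and 1 adjusted over the list alone; adjusted p = 0.535 with an estimated correlation), lost without wild-type vehicle 4 (0.073) or knockout vehicle 5 (0.074), and of the mitochondrially encoded proteins (median -0.25, 0 of 13; adjusted p = 0.785 with an estimated correlation), lost without knockout clozapine 3 (0.10). The mitochondrial median was 0.01 after the length and GC correction (adjusted p = 0.988).

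Other cells and ribosomal protein genes also took part in the interaction. Oligodendrocyte markers had a median of -0.23 (0 of 11; adjusted p = 0.785 with an estimated correlation), and the call ended without wild-type vehicle 1 (0.10), wild-type clozapine 3 (0.051), knockout vehicle 2 (0.052) or knockout clozapine 3 (0.22). Red blood cell genes had a median of -0.64 (0 of 5; adjusted p = 0.785 with an estimated correlation), lost without wild-type vehicle 3 (0.082), wild-type vehicle 4 (0.13), wild-type clozapine 3 (0.47), knockout vehicle 4 (0.11), knockout vehicle 5 (0.13), knockout clozapine 3 (0.053) or knockout clozapine 5 (0.37). Ribosomal protein genes had a median of -0.04 (0 of 75; adjusted p = 0.925 with an estimated correlation), lost without wild-type vehicle 3 (0.67), wild-type clozapine 2 (0.78), knockout vehicle 2 (0.052), knockout vehicle 5 (0.54) or knockout clozapine 5 (0.11). The red blood cell and ribosomal calls ended after the length and GC correction too (adjusted p = 0.0506 and 0.731). Across genes, which are not independent replicates, the clozapine effects in the genotypes had a Pearson correlation of -0.01 and a Spearman correlation of -0.03. Of the genes called in either genotype, 61 (42.1%) had the same direction in both, against 48.1% of all tested genes.

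Averaged over the genotypes, edgeR called Vgf lower and Kalrn higher with clozapine. Chance is not excluded for the count of calls in this comparison, as described in the last section. Vgf, the precursor of secreted neuropeptides, was at 523 ± 19.4 and 342 ± 32.5 CPM in wild type and at 444 ± 19.5 and 382 ± 45.6 CPM in the labelled knockout (vehicle and clozapine, SD, n = 3 each; averaged log2 change -0.42, SE 0.06, edgeR adjusted p = 0.011). Its call and that of Nr1d1 (averaged change -0.28, edgeR adjusted p = 0.011) ended without wild-type vehicle 3 (0.063 for both). Kalrn, an exchange factor that shapes dendritic spines, rose by 0.27 (edgeR adjusted p = 0.030), but not without wild-type vehicle 3 (0.088), wild-type clozapine 2 (0.062), wild-type clozapine 5 (0.061), knockout vehicle 2 (0.052), knockout clozapine 3 (0.058), knockout clozapine 4 (0.082) or knockout clozapine 5 (0.074), or after the length and GC correction (0.12). Of 26 genes called by edgeR's quasi-likelihood test, 17 higher and 9 lower, 2 passed in all 12 tests that left out 1 library. These were S100a6, which encodes a calcium-binding protein (change -0.37, edgeR adjusted p = 0.0095), and the kinase gene Pak7 (0.34, edgeR adjusted p = 0.0095), both named after their values were seen. Groups of 6 did not overlap for 0.376% of genes, where chance gives 0.216%. The count was 2 without wild-type vehicle 3, 4 without knockout clozapine 5 or knockout vehicle 2, 5 without knockout clozapine 4, 6 without wild-type clozapine 2, 10 without wild-type vehicle 4, 13 without wild-type clozapine 3 or 5, 15 without knockout clozapine 3 or knockout vehicle 4, and 16 without wild-type vehicle 1. More genes were lower than higher without wild-type vehicle 1 or 4, wild-type clozapine 2, knockout vehicle 2, or knockout clozapine 4 or 5. DESeq2 called 162 genes, limma-voom 7, edgeR with no low-count filter 157 (76 higher and 81 lower), with 1 surrogate variable 72, and a threshold of 0.10 gave 65.

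Cholesterol synthesis and channel genes were called upward after clozapine in the average, but the genotypes differed. The first had a median of 0.19 in wild type and of -0.04 in the labelled knockout, where camera did not call it (adjusted p = 0.227). Its averaged median was 0.08 (0 of 25, 2 higher adjusted over the list alone; adjusted p = 0.548 with an estimated correlation). The second had medians of 0.02 in wild type, not called (camera adjusted p = 0.806), 0.16 in the labelled knockout and 0.05 averaged (0 of 17, 5 higher adjusted over the list alone; adjusted p = 0.548 with an estimated correlation). The unfolded protein response joined a median of -0.19 in wild type with 0.07 in the labelled knockout, not called there (camera adjusted p = 0.377), to a median of -0.08 with 1 of 16 falling, Hspa5 (3 adjusted over the list alone; adjusted p = 0.548 with an estimated correlation). The averaged Hspa5 change was -0.21 (edgeR adjusted p = 0.037), and its call ended with limma-voom (0.057) and without any 1 library except wild-type vehicle 4 and knockout vehicle 5, with adjusted p from 0.050 (wild-type clozapine 3) to 0.11 (knockout clozapine 5) by the same edgeR test. Meningeal fibroblast markers (median 0.24, from 0.26 in wild type and 0.29 in the labelled knockout, 0 of 8, 2 adjusted over the list alone) and red blood cell genes (median 0.54, from 0.86 and 0.22, 0 of 5) were called upward as well (adjusted p = 0.548 with an estimated correlation for both). Choroid plexus markers had a median of -0.57 (from -1.04 and -0.26, 0 of 5, 1 lower adjusted over the list alone; adjusted p = 0.548 with an estimated correlation), lost without knockout vehicle 5 (0.054) or knockout clozapine 4 (0.058). Interneuron markers had a median of 0.07 (from 0.01 and 0.13, 0 of 13, 2 higher adjusted over the list alone; adjusted p = 0.548 with an estimated correlation), lost without wild-type clozapine 5 (0.052) or knockout vehicle 4 (0.13). Mitochondrially encoded proteins had a median of -0.09 (from 0.02 and -0.21, 0 of 13; adjusted p = 0.736 with an estimated correlation), lost without wild-type vehicle 1 (0.31) or knockout clozapine 3 (0.34). Glucocorticoid-responsive genes had a median of -0.07 (from -0.06 and -0.09, 0 of 16, 2 lower adjusted over the list alone; adjusted p = 0.746 with an estimated correlation), lost without wild-type vehicle 3 (0.051), wild-type vehicle 4 (0.34), wild-type clozapine 2 (0.11), wild-type clozapine 5 (0.052), knockout vehicle 5 (0.49), knockout clozapine 3 (0.30) or knockout clozapine 5 (0.13). By genotype, camera did not call the interneuron, mitochondrial and glucocorticoid lists in wild type (adjusted p = 0.731, 0.806 and 0.523). In the labelled knockout it did not call those of choroid plexus, red blood cells and glucocorticoid response (adjusted p = 0.207, 0.482 and 0.053). The mitochondrial and glucocorticoid calls ended after the length and GC correction (adjusted p = 0.0567 for both).

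The baseline effect of the labelled knockout was compared in mice given vehicle. Lbhd2 (ENSMUSG00000087075.1, chromosome 12, 111406809 to 111412090) rose from 0.361 ± 0.059 to 3.65 ± 0.312 CPM (SD, n = 3 each; log2 change 3.31, SE 0.20, edgeR adjusted p = 2.7e-07). Ppm1j, a protein phosphatase gene, rose from 0.822 to 3.26 CPM (log2 change 1.98, edgeR adjusted p = 2.2e-05), and Stag3, a cohesin subunit of meiotic cells, from 1.01 to 4.005 CPM (1.98, edgeR adjusted p = 0.00012). Hspa5 fell from 371 ± 24.6 to 222 ± 4.87 CPM (log2 change -0.74, SE 0.05, edgeR adjusted p = 7.5e-07). Among synaptic genes, Shank2, a scaffold of the postsynaptic density, fell by 0.59 (edgeR adjusted p = 0.00037) and Cbln4, a secreted synapse organiser, from 50.5 to 17.0 CPM (log2 change -1.56, edgeR adjusted p = 0.0028). The deacetylase genes Hdac4 and Hdac5 fell by 0.43 and 0.28 (edgeR adjusted p = 0.00085 and 0.0057). Each gene named so far in this comparison passed in all 12 tests that left out 1 library, as did 492 of the 1584 called genes in total. In total edgeR's quasi-likelihood test called 1584 genes, 693 higher and 891 lower, and the 3 libraries of each group did not overlap for 27.3% of genes, where chance gives 10%. The count was 617 without wild-type vehicle 3, 837 without knockout vehicle 2, 943 without knockout vehicle 5 (476 higher and 467 lower) and 954 without wild-type vehicle 1, and a threshold of 0.10 gave 2480.

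Chaperone genes were lower and cholesterol synthesis genes higher in the labelled knockout under vehicle. Of 16 genes of the unfolded protein response 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -0.29 (camera adjusted p = 4e-15; adjusted p = 0.0976 with an estimated correlation). Beside Hspa5, Pdia6 fell by 0.51 (edgeR adjusted p = 7.2e-05), Calr by 0.40 and Sdf2l1, a chaperone cofactor gene, by 0.94 (edgeR adjusted p = 0.00012 for both). Of 11 heat shock genes 4 fell (6 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.125 with an estimated correlation), including Hspb1 with a change of -0.98 (edgeR adjusted p = 0.00014) and Hsph1 with -0.32 (edgeR adjusted p = 0.0019). Of 25 cholesterol synthesis genes 15 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 3.6e-11; adjusted p = 0.125 with an estimated correlation). Insig1, which senses sterols, rose by 0.51 (edgeR adjusted p = 0.00052). The 6 members named here beside Hspa5 held in every test that left out 1 library. The oligodendrocyte markers, whose cells make much cholesterol, had a median of -0.01 in this comparison and were not called.

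Activity-dependent and channel genes were lower in the same comparison. Of 20 immediate early genes, which neurons switch on when active, 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00023; adjusted p = 0.852 with an estimated correlation). Egr3 fell from 181 to 91.0 CPM (log2 change -0.99, edgeR adjusted p = 0.012). Jun, with 0.59, was the member that rose (edgeR adjusted p = 0.030), a call lost without wild-type vehicle 1 (0.067), wild-type vehicle 3 (0.11), knockout vehicle 2 (0.076), knockout vehicle 4 (0.062) or knockout vehicle 5 (0.098), and with no low-count filter (0.079). Of 17 channel genes 5 fell (9 lower and 1 higher adjusted over the list alone), with a median of -0.18 (adjusted p = 0.852 with an estimated correlation). Of 28 excitatory synapse genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.07 (adjusted p = 0.889 with an estimated correlation), a call lost without knockout vehicle 5 (0.19). Upper-layer markers had a median of -0.18 with 2 of 6 falling (3 adjusted over the list alone; adjusted p = 0.87 with an estimated correlation), a call lost without wild-type vehicle 1 (0.32) or knockout vehicle 4 (0.15). Ribosomal protein genes had a median of 0.07 with 1 of 75 rising (0 adjusted over the list alone; adjusted p = 0.92 with an estimated correlation), a call lost without wild-type vehicle 3 (0.22) or knockout vehicle 5 (0.24). The last 3 calls ended after the length and GC correction (adjusted p = 0.0969, 0.0969 and 0.55).

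The labelled genotypes were also compared in mice given clozapine, where clock genes differed; the hour of tissue collection is not stated. Dbp was at 64.8 ± 4.16 CPM in wild type and 132 ± 11.3 CPM in the labelled knockout (SD, n = 3 each; log2 difference 1.03, SE 0.07, edgeR adjusted p = 5.5e-07). Ciart, a repressor of the clock, and Nr1d1 were higher by 1.17 and 0.55 (edgeR adjusted p = 0.0010 and 0.00013), and the clock activator Arntl and the repressor Nfil3 had differences of -0.49 and -0.73 (edgeR adjusted p = 0.0013 and 0.0062). Lbhd2, Ppm1j and Stag3 were again higher, by 2.94, 2.13 and 2.07 (edgeR adjusted p = 9e-07, 2.1e-05 and 0.00083). These 8 genes passed in all 12 tests that left out 1 library. In total edgeR's quasi-likelihood test called 345 genes, 256 higher and 89 lower, of which 56 passed in all 12 such tests. For 22.5% of genes the libraries did not overlap, where chance gives 10%. The count was 59 without knockout clozapine 3, 126 without wild-type clozapine 3, 165 without knockout clozapine 5, 192 without wild-type clozapine 5 and 197 without knockout clozapine 4. DESeq2 called 547 genes, edgeR with no low-count filter 566, with 1 surrogate variable 547, and a threshold of 0.10 gave 697.

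Of 17 circadian clock genes 4 were higher and 2 lower in the labelled knockout under clozapine (5 and 4 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00015; adjusted p = 0.401 with an estimated correlation). Of 11 heat shock genes 2 were lower (4 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.36 with an estimated correlation). They were Dnaja1 with -0.25 (edgeR adjusted p = 0.011, but 0.077 without knockout clozapine 3) and Hspb1 with -0.52 (edgeR adjusted p = 0.034). The Hspb1 call ended without wild-type clozapine 2 (0.11), wild-type clozapine 3 (0.072), knockout clozapine 3 (0.085), knockout clozapine 4 (0.12) or knockout clozapine 5 (0.089), and with limma-voom (0.056). Oligodendrocyte markers had a median of -0.25 with 1 of 11 lower (4 adjusted over the list alone; adjusted p = 0.807 with an estimated correlation). It was Ermn, a myelin sheath gene, with -0.71 (edgeR adjusted p = 0.021), lost without wild-type clozapine 3 (0.072), knockout clozapine 3 (0.072) or knockout clozapine 5 (0.061). Immediate early genes had a median of -0.22 (0 of 20, 3 lower adjusted over the list alone; adjusted p = 0.807 with an estimated correlation), lost without knockout clozapine 5 (0.25). The unfolded protein response had a median of -0.11 (0 of 16; adjusted p = 0.807 with an estimated correlation), lost without wild-type clozapine 2 (0.18) or knockout clozapine 5 (0.17). The genotype effects under vehicle and under clozapine correlated across genes with a Pearson r of 0.31 and a Spearman r of 0.27, and 119 genes were higher and 22 lower in both, where independent calls would share 10.3 and 4.59. Genes are not independent replicates in such a correlation.

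**Figure D4:**
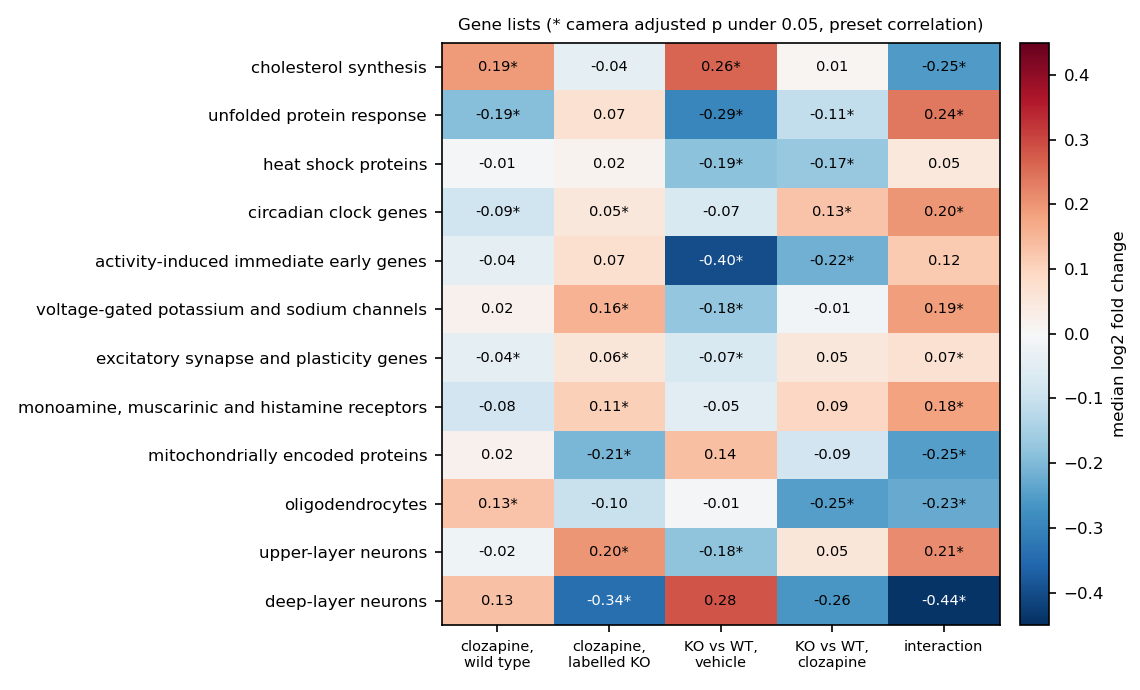
Median log2 fold change (colour) of 12 gene lists (vertical axis) in 5 comparisons (horizontal axis), with a star where camera gave an adjusted p under 0.05 with its preset correlation. The unfolded protein response is at -0.19 for clozapine in wild type and -0.29 for the labelled knockout under vehicle, and cholesterol synthesis at 0.19 and 0.26.

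Averaged over the treatments, the labelled knockout differed from wild type at the largest number of genes in the fit of all 12 libraries. More genes passed under vehicle than in the average without knockout clozapine 3 (1427 against 1152), wild-type clozapine 3 (1611 against 1312) or wild-type clozapine 2 (1722 against 1718). Lbhd2 was higher by 3.13 on the log2 scale (SE 0.15, edgeR adjusted p = 1.8e-09), Ppm1j by 2.05 (edgeR adjusted p = 1.4e-07) and Stag3 by 2.03 (edgeR adjusted p = 6.3e-06). Hspa5 was lower, with a difference of -0.45 (SE 0.04, edgeR adjusted p = 4.1e-06), as was Synj2, a phosphatase of membrane lipids, with -0.59 (edgeR adjusted p = 4.1e-05). Clock genes went both ways: Dbp had a difference of 0.62 (edgeR adjusted p = 1.6e-06), and Npas2 and Arntl, partners of the clock's activating complex, had -0.47 and -0.40 (edgeR adjusted p = 0.00013 and 0.00010). These 8 genes passed in all 12 tests that left out 1 library. In total edgeR's quasi-likelihood test called 1821 genes, 955 higher and 866 lower, of which 963 passed in all 12 such tests. For 4.04% of genes there was no overlap between 6 and 6 libraries, where chance gives 0.216%. The count was 1152 without knockout clozapine 3, and a threshold of 0.10 gave 2782. More genes were lower than higher with DESeq2 (877 higher and 948 lower), after the length and GC correction (958 and 988), at a threshold of 0.10 (1390 and 1392) and without knockout vehicle 4 (823 and 875).

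Of 16 genes of the unfolded protein response 9 were lower in that average (9 adjusted over the list alone), with a median of -0.26, from -0.29 under vehicle and -0.11 under clozapine (camera adjusted p = 5.9e-12; adjusted p = 0.0913 with an estimated correlation). Of 11 heat shock genes 6 were lower (6 adjusted over the list alone), with a median of -0.17, from -0.19 and -0.17 (adjusted p = 0.0913 with an estimated correlation), such as Hspb1 with -0.75 and Hspa8 with -0.23 (edgeR adjusted p = 5.3e-05 and 0.0017). Of 20 immediate early genes 5 were lower and 1, Jun, higher (5 and 1 adjusted over the list alone), with a median of -0.37, from -0.40 and -0.22 (adjusted p = 0.663 with an estimated correlation). Fosl2 had a difference of -0.96 and Fosb of -0.74 (edgeR adjusted p = 0.0040 and 0.0064). Of 25 cholesterol synthesis genes 8 were higher (15 higher and 1 lower adjusted over the list alone), with a median of 0.11 (adjusted p = 0.569 with an estimated correlation) that combines 0.26 under vehicle with 0.01 under clozapine, where camera did not call the list (adjusted p = 0.784), and Insig1 had 0.32 and Mvd 0.31 (edgeR adjusted p = 0.00081 and 0.0015). Oligodendrocyte markers had a median of -0.12, from -0.01 and -0.25, with 2 of 11 lower (4 adjusted over the list alone; adjusted p = 0.904 with an estimated correlation), lost without wild-type vehicle 3 (0.053), wild-type vehicle 4 (0.052), wild-type clozapine 2 (0.074), wild-type clozapine 3 (0.056), knockout vehicle 5 (0.081) or knockout clozapine 3 (0.10). Channel genes had a median of -0.10, from -0.18 and -0.01, with 3 of 17 lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.904 with an estimated correlation), lost without wild-type vehicle 3 (0.053), wild-type clozapine 2 (0.062), wild-type clozapine 3 (0.081) or knockout vehicle 5 (0.21). Ribosomal protein genes had a median of 0.04, from 0.07 and 0.02, with 1 of 75 higher (1 adjusted over the list alone; adjusted p = 0.904 with an estimated correlation), lost without wild-type vehicle 3 (0.26), wild-type clozapine 3 (0.11), wild-type clozapine 5 (0.11) or knockout vehicle 5 (0.38). By treatment, camera did not call the oligodendrocyte list under vehicle (adjusted p = 0.724) or the channel and ribosomal lists under clozapine (adjusted p = 0.959 and 0.473). The channel and ribosomal calls ended after the length and GC correction (adjusted p = 0.146 and 0.566).

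Genes near Hdac2 were compared with the rest because DNA around a targeted gene can come from another strain. Within 10 Mb of Hdac2, 8 of 91 tested genes (8.79%) differed between the labelled genotypes in the average, against 1813 of 17195 elsewhere (10.5%; 2-sided Fisher's exact p = 0.732, odds ratio 0.818, 95% interval 0.341 to 1.69).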

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

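The tests of explanations and the splits of the samples in this part were chosen only after the results were seen; the interaction test was planned. For 113 genes the effect of clozapine differed between the labelled genotypes by edgeR's quasi-likelihood test of the interaction. Of 100 splits of the libraries, the real one included, 1 gave as many genes, and the highest of the others gave 55. The other splits were drawn at random and regrouped the treatments within each genotype. They argue against such a count arising with no treatment difference in either genotype. They do not by themselves test equal effects of clozapine in the genotypes. Nor do they separate the drug from other differences between the groups, such as the inherited ones raised below. Removing single libraries moved the count to between 13 (knockout clozapine 5) and 181 (knockout vehicle 4). It was 19 without wild-type vehicle 3, 21 without knockout clozapine 3, 23 without wild-type clozapine 5, 24 without knockout clozapine 4, 40 without knockout vehicle 5, and 54 without wild-type vehicle 1 or knockout vehicle 2.

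The 24 named genes whose clozapine effect differed have varied functions. The log2 difference was positive for the clock gene Dbp (0.81), for Eln, which encodes elastin (1.04), the receptor kinase gene Epha8 (0.90), the kinase gene Prkg2 (0.96), Fibcd1 (0.77), Fstl4 (0.71), Sh2b2 (0.80), Shc3 (0.66), Pcdhac2 (0.66), Ankrd6 (0.66), Zbtb40 (0.77) and Acp1 (1.07). It was negative for the chemokine gene Ccl28 (-2.09), the serotonin receptor gene Htr2c (-0.86), the ephrin gene Efnb3 (-0.59), Gpx3 (-0.94), Hpcal1 (-0.60), Rprm (-1.38), Myh3 (-1.26), Tmem267 (-1.78), Adi1 (-1.32), the Y-linked Eif2s3y (-1.27), and Rn7s1 (-2.80) and Rn7s2 (-2.79), whose reads are shared. Adi1 is in the crowded stretch of chromosome 12 described below and Acp1 lies near it. Tmem267 and Ccl28 lie beside Nnt on chromosome 13, which is in steps across libraries. An inherited difference between mice was therefore not separated from the drug effect for these 4 genes. Steps were also seen at Odc1 on chromosome 12, outside that stretch, so a place outside it clears no gene. For the rest of the 24, Hpcal1 among them, an inherited difference was not tested. Asap2 and 3110053B16Rik, also called in the stretch of chromosome 12, were among the 12 interaction calls kept in all 12 fits that left out 1 library. Of these 24 genes Dbp, Eln, Rn7s1 and Rn7s2 passed edgeR's test in all 12 fits that left out 1 library, while DESeq2 left Rn7s1 and Rn7s2 out by its low-count filter. Without knockout clozapine 5 the other 20 all missed the threshold, with edgeR adjusted p from 0.055 (Adi1, Ankrd6, Htr2c, Sh2b2) to 0.098 (Pcdhac2, Prkg2), and the removal of at least 1 further library ended each of these 20 calls too, with values up to 0.13 (Fstl4 without knockout clozapine 3). Other settings ended calls as well. Of 50 gene results in the interaction, these 24 among them, limma-voom ended 7, the length and GC correction 11 and the replicate block 26.

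The same interaction test differed for 12 lists by camera at the preset correlation and for 0 with an estimated correlation, where the smallest adjusted p was 0.29. The median log2 difference was -0.25 for cholesterol synthesis, 0.24 for the unfolded protein response, 0.20 for circadian clock genes, 0.18 for monoamine, muscarinic and histamine receptors, 0.19 for voltage-gated potassium and sodium channels and 0.0684 for excitatory synapse genes. It was 0.21 for upper-layer and -0.44 for deep-layer neuron markers, -0.25 for mitochondrially encoded proteins, -0.0409 for ribosomal proteins, -0.23 for oligodendrocyte markers and -0.64 for red blood cell genes. Camera calls ended without wild-type vehicle 4 (adjusted p = 0.073) or knockout vehicle 5 (0.074) for the receptors, and without knockout clozapine 3 (0.10) for the mitochondrially encoded proteins. They ended without wild-type vehicle 1 (0.10), wild-type clozapine 3 (0.051), knockout vehicle 2 (0.052) or knockout clozapine 3 (0.22) for oligodendrocytes. For ribosomal proteins they ended without wild-type vehicle 3 (0.67), wild-type clozapine 2 (0.78), knockout vehicle 2 (0.052), knockout vehicle 5 (0.54) or knockout clozapine 5 (0.11). Red blood cell genes lost theirs without wild-type vehicle 3 (0.082), wild-type vehicle 4 (0.13), wild-type clozapine 3 (0.47), knockout vehicle 4 (0.11), knockout vehicle 5 (0.13), knockout clozapine 3 (0.053) or knockout clozapine 5 (0.37).

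Unfolded protein response genes were lower and cholesterol synthesis genes higher than in wild-type vehicle both after clozapine in wild type and in the labelled knockout under vehicle. A trend with gene length and GC content is argued against as the whole cause, since the unfolded protein response kept medians of -0.18 and -0.33 and its camera call after the correction. A larger share of oligodendrocytes stays undecided as a source of the higher cholesterol genes after clozapine in wild type. Their markers had a median of 0.13 there, below that of the cholesterol genes but by less than 2 SE of the markers. For the labelled knockout the marker median was -0.0075, without a rise. The SE is over marker genes, not libraries, so the test decides neither case. The bound was moved from 1 to 2 SE after a first outcome was seen, and the wild-type gap exceeded 1 SE. It stays open whether the wild-type vehicle libraries alone set the difference, since labelled knockout against wild type under clozapine, without them, had a median of -0.11 for the unfolded protein response, called at the preset correlation only, and of 0.0074 for cholesterol synthesis, not called (camera adjusted p = 0.784); a biological effect of drug and genotype stays open too.

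Averaged over treatments, Hdac2 was not lower in the labelled knockout libraries. Labels mixed at random are argued against: 4.04% of genes had no overlap between 6 and 6 libraries (0.216% by chance). Other label errors stay open. Transcripts that keep the counted exons could leave the gene's count level, with a fall of at most 3.53% within the 95% interval. No value in counts per gene tells this apart from an unchanged gene.

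Genes on chromosomes 18 and 12 lay in steps across libraries, and these genes were chosen after their values were seen. Tpgs2 (ENSMUSG00000024269.11, chromosome 18, 25127223 to 25169007) and the neighbouring AW554918 were at 0.53 and 0.50 of the mean of wild-type clozapine and knockout vehicle in the knockout clozapine libraries, and at 0.0247 and 0.0113 of it in wild-type vehicle 1, while Fhod3 and Celf4 beside them stayed at 0.856 to 1.11, so an inherited deletion in 1 or 2 copies is a candidate explanation. Low quality of these libraries is argued against by those neighbours, whose lowest ratio in them was 0.856; a median over the chromosome's genes decides nothing, since scaling of the libraries centres it. Families shared within groups may be part of it and stay open: of 246 bins of 10 Mb, by Fisher's exact test, 0 passed for averaged genotype calls (smallest adjusted p = 0.0741), 0 for averaged clozapine (0.144) and 0 for the genotypes under clozapine (0.221), but 2 did for the genotypes under vehicle (0.0127, a bin with fewer calls, 2 of 152), 1 for clozapine in wild type (0.0033, chromosome 12 from 20 Mb, 5 of 38) and 1 in the labelled knockout (0.0052, the bin of Rn7s1 and Rn7s2). For the interaction 2 bins passed, and in the first, on chromosome 12 from 20 Mb, 6 of 38 genes were called (adjusted p = 3.9e-05, Fisher's exact test). Their spread within groups was at a median percentile of 72.5 among genes of like expression, against 58.0 for the other 107 calls. In knockout vehicle 5, 3110053B16Rik was at 13.1 CPM, against 7.67 and 8.30 CPM in knockout vehicle 2 and 4. It was at 14.6 to 16.8 CPM in wild-type vehicle and knockout clozapine. Adi1 was at 23.1 CPM in knockout vehicle 5, against 33.6 and 28.5 CPM. Kidins220 and Eipr1, also called there, had spread percentiles of only 16.2 and 5.32. An inherited block carried by some mice is thus a candidate and stays open.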

How the results depend on the processing

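The correction for gene length and GC content and the unrounded counts were chosen only after seeing the data; the other alternatives were planned. Of the named genes, Hdac2, which passed in no comparison, was the only one to change sign. The interaction median of the mitochondrially encoded proteins, -0.25, became 0.01 after the length and GC correction. The balance of higher and lower genes turned for averaged genotype (955 and 866) with DESeq2 (877 and 948), the length and GC correction (958 and 988), a threshold of 0.10 (1390 and 1392) and without knockout vehicle 4 (823 and 875). For averaged clozapine (17 and 9) it turned with no low-count filter (76 and 81), the replicate block (27 and 34), and without wild-type vehicle 1 (6 and 10), wild-type vehicle 4 (4 and 6), wild-type clozapine 2 (2 and 4), knockout vehicle 2 (1 and 3), knockout clozapine 4 (2 and 3) or knockout clozapine 5 (1 and 3). For the genotypes under vehicle (693 and 891) it turned without knockout vehicle 5 (476 and 467). The 30 lists called up and 32 down are near balance, and 8 of the 12 removals gave more up than down. For clozapine in wild type (141 genes) DESeq2 called 285, no low-count filter 304, the replicate block 18, a threshold of 0.10 260, and the 2 groups alone 92. For clozapine in the labelled knockout (4 genes) DESeq2 called 285, limma-voom 2, RLE size factors 2, no filter 213, the block 174, 1 surrogate variable 209, a threshold of 0.10 113, the 2 groups alone 7, and the length and GC correction 2. The difference between 141 and 4 was thus not kept with DESeq2, the block or the surrogate variable. It was proportionally much smaller with no filter (304 and 213) and at a threshold of 0.10 (260 and 113). For the genotypes under vehicle (1584) the block gave 385 and a threshold of 0.10 2480. Under clozapine (345) DESeq2 gave 547, no filter 566, the surrogate variable 547 and 0.10 697. For the interaction (113) DESeq2 gave 354, no filter 302, the block 12, the surrogate variable 290, 0.10 258, and the length and GC correction 60. For averaged clozapine (26) DESeq2 gave 162, limma-voom 7, no filter 157, the block 61, the surrogate variable 72 and 0.10 65, and for averaged genotype (1821) 0.10 gave 2782. Of the 245 list tests camera called 62, 0 with an estimated correlation, and fry 11. A looser threshold and fewer libraries change counts by construction; for the rest the cause was not tested. Leaving out 1 library gave 20 to 219 genes for clozapine in wild type, 0 to 25 in the labelled knockout, 617 to 1722 for the genotypes under vehicle, 59 to 425 under clozapine, 13 to 181 for the interaction, 2 to 24 for averaged clozapine and 1152 to 1870 for averaged genotype. It gave 49 (without knockout vehicle 5) to 67 (without wild-type vehicle 4) list calls. The correlation of the clozapine effects, -0.01, lay around 0, at -0.079 (without knockout clozapine 5) to 0.025 (without wild-type clozapine 5). The report names the libraries that moved a gene count by over 1.5 times; the highest counts it does not name, within that bound, were 1722 without wild-type clozapine 2, 425 and 24 without knockout vehicle 5 and 1870 without wild-type vehicle 4. Where an arm is left with 2 libraries, they are assumed to vary like the other groups. The odds ratio near Hdac2 stayed at 0.79 to 0.83 with windows of 5 and 20 Mb and a threshold of 0.10. Of 406 gene results, counting each named gene in each comparison, limma-voom ended 35 calls and added 5, DESeq2 ended 11, counting genes to which its filter gave no adjusted p, and added 82, RLE ended 5 and added 1, no filter ended 16 and added 59, the surrogate variable ended 3 and added 47, the block ended 130 and added 28, and the length and GC correction ended 31 and added 10. Unrounded counts left all 406 on their side of the threshold. The scaling alternatives shifted the median gene by at most 0.02 on the log2 scale. Same-numbered libraries of different groups correlated at -0.0803 to 0.123 over 10 pairs of libraries, so the numbers do not pair them and the block is no better test. In simulated counts 11.9% of the smallest changes were called in the interaction and 59.7% in averaged clozapine, at the libraries' own depths; neither depth nor the number of libraries was varied.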

Other observations

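The splits of the samples in this part, and the choice of S100a6, Pak7, Nnt and Ttr, were made only after the results were seen; the receptor, deacetylase and cell lists were planned. Of 19 receptor genes of the kinds clozapine binds, 1 rose and 3 fell in the labelled knockout under vehicle (2 and 4 adjusted over the list alone), and camera did not call the list (median -0.05, adjusted p = 0.528). Htr2c, a serotonin receptor gene, rose by 0.82 on the log2 scale (edgeR adjusted p = 0.0010), and the adrenergic receptor genes Adra2c and Adra1d fell by 0.49 and 0.46 (edgeR adjusted p = 0.00034 and 0.0042). The histamine receptor gene Hrh1 fell by 0.56 (edgeR adjusted p = 0.0019). Averaged over treatments, Hrh3 had a difference of 0.38 (edgeR adjusted p = 0.0058), the glutamate receptor gene Grm2 0.34 (0.0056 by the same edgeR test, adjusted) and the GABA receptor gene Gabra3 0.21 (0.0051). Relb of the NF-kB pathway was lower (-0.36, edgeR adjusted p = 0.015), and the precursor markers of oligodendrocytes went both ways, with Pdgfra higher (0.30, edgeR adjusted p = 0.00068) and Olig2 lower (-0.19, edgeR adjusted p = 0.046). The Olig2 call ended with limma-voom (0.052) and in 10 of the 12 removals of 1 library, all but those of wild-type clozapine 5 and knockout clozapine 5, with edgeR adjusted p up to 0.11, and camera did not call the list.

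In contrast to these single genes, 14 tested lists were not called by camera in any of the 7 comparisons. Their medians ranged from -0.06 to 0.04 for histone deacetylases, -0.07 to 0.07 for the NF-kB pathway, 0.01 to 0.08 for metabotropic glutamate receptors, 0.01 to 0.07 for fatty acid synthesis and -0.03 to 0.02 for the nuclear-encoded respiratory chain. They ranged from -0.04 to 0.08 for excitatory neurons, -0.04 to 0.07 for astrocytes, -0.11 to 0.14 for oligodendrocyte precursors, -0.17 to 0.09 for endothelial, -0.10 to 0.11 for mural and -0.31 to 0.12 for ependymal cells. For neurons of other regions they ranged from -0.14 to 0.15 (striatal projection), -0.15 to 0.37 (olfactory bulb) and -0.17 to 0.07 (thalamic). The smallest camera adjusted p among the 14 was 0.0652, for metabotropic glutamate receptors.

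S100a6 fell by 0.55 and Pak7 rose by 0.51 with clozapine in wild type (edgeR adjusted p = 0.0023 and 0.0011), and their changes in the labelled knockout were -0.19 and 0.17 (edgeR adjusted p = 0.24 and 0.25). The interaction did not pass for S100a6 (edgeR adjusted p = 0.12) or Pak7 (0.089). Pak7 was at 60.5 to 64.3 CPM with vehicle and 83.2 to 91.8 CPM with clozapine in wild type, and at 65.9 to 70.1 and 69.5 to 80.3 CPM in the labelled knockout. Nnt, which encodes a mitochondrial transhydrogenase, lay at 39.6, 35.8 and 19.6 CPM in wild-type vehicle, 17.1, 26.0 and 26.8 CPM in wild-type clozapine, 28.9, 18.8 and 36.0 CPM in knockout vehicle, and 27.9, 18.8 and 39.0 CPM in knockout clozapine. Ttr was at 53.3 CPM in wild-type vehicle 3 alone.

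For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. As many genes were called in 1 split, the real one, in each: 141 against a highest other of 0 for clozapine in wild type, 4 against 0 in the labelled knockout, 1584 against 1 for the genotypes under vehicle and 345 against 1 under clozapine. For averaged genotype, 1 of 100 splits, the others drawn at random, gave as many genes (1821 against a highest other of 300). A random grouping of these libraries is thus argued against at 0.05, whatever sets the groups apart. For averaged clozapine 2 of 100 did (26 against 55). A split that was not drawn, with the treatments of the labelled knockout exchanged, equals the interaction test, which called 113 genes. Chance is therefore not excluded for the averaged clozapine count. What the split with 55 genes separates was not tested. Wild-type clozapine and knockout vehicle effects share the wild-type vehicle libraries: their correlation across genes was 0.463, against a mean of 0.498 and a highest of 0.537 in 20 simulations without any effect, and their covariance was 0.0323 against 0.0198. The simulations drew genes independently, without the trends with gene length and GC content seen in these comparisons. The higher covariance therefore does not show a shared effect. Genes are not independent replicates, and 3 control libraries cannot be divided to remove the shared part.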
